A study of Mus musculus with 6 samples.

How the data were processed

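Total RNA of cultured peritoneal macrophages was labelled as biotinylated cRNA for an Affymetrix expression array, per the labels' protocols. The values used were a table of 28815 probes on 6 arrays, deposited by the authors on a log scale. How probes were summarized, corrected for background and normalized, and the log base, are not given in the sources used here; values were taken as log2. In the deposited log2 values each probe's median over the 6 arrays had been subtracted (the largest remaining probe median was 5e-07), so they hold no signal level and no probe can be compared with another. Array medians lay between -0.0049 and 0.0072, and the values were used as deposited, with no column left out.

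The single-precision steps of the numbers still show which probes lay at 8 or above on all arrays before centring. This held for 7884 probes (27.4%), for 92.6% of 216 ribosomal protein probes and for 1.35% of 1035 olfactory receptor probes, the usual size of log2 array values. The same read from control and PAM arrays alone held for 10406 probes, and takes in more dim ones (12.7% of olfactory receptor probes). Both classes were used only for checks, in the closing section and for genes moved by both ligands.

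Probes were named from the platform annotation: 21780 had 1 gene symbol, 1605 had several and 5430 had none. Of the single-gene probes 21689 were found in a current gene table by their Entrez identifier, and 0 symbols changed. Probes with several symbols or none stayed out of gene counts. Genes with more than 1 probe (998 of 19935) were given the mean of their probes; probes of Eif4e, Ppp1r12b and Sash1 passed in opposing directions with poly I:C, and those of Ppp2r5c between the ligands.

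The tests were written before the data were examined and changed where the centred values required it. A filter on dim probes and the choice of the brightest probe per gene need signal levels, so all probes were kept and averaged. A variance trend over the mean level has no meaning on centred values, so limma's eBayes was run without trend, and with trend as an alternative. One mean per group was fitted with lmFit over all 6 arrays (3 residual and 5.68 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. Tools were limma 3.58.1 in R 4.3.3, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

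Gene lists, 32 in number and fixed beforehand, were tested with camera in 3 comparisons, adjusting over 96 tests. A preset correlation was used, and again an estimated one, with which no list kept its call. The run with the estimated correlation has little power at 3 residual degrees of freedom. Even the interferon-stimulated list, with all 41 genes higher with poly I:C, had an unadjusted camera p of 0.0223 there. A call lost in that run therefore does not show that a list did not move. Members were counted after adjustment over all genes and after adjustment over the list alone. Genes named in the text were, for each comparison, the 10 with the largest increase and the 10 with the largest decrease among those past the threshold whose arrays did not overlap. To these came up to 2 members per list and direction, 20 genes per direction of opposite response ranked by the smaller of their changes, and 12 genes always reported where measured.

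On simulated data with the real residual spread of all 19935 genes, the poly I:C comparison passed 71% of genes changed 1.5-fold. It passed 94% of those changed 2-fold, 100% of those changed 4-fold and 5 of 19735 unchanged genes. The changed genes numbered 100 at 1.5-fold, 50 at 2-fold and 50 at 4-fold, whereas 6059 genes passed with poly I:C in the data. The cutoff of the adjustment loosens as more genes change, so these shares and the 5 false calls do not describe the real comparison. Alternatives were centring of arrays, the variance trend with and without robust fitting, only the 4 arrays compared, the replicate number as a block, leaving out each array, fold minimums and the estimated correlation. Added after seeing the data were each probe on its own and genes at 8 or above on all arrays. Dixon's test and counts of other sample splits do not apply to groups of 2.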

Results

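Gene expression was measured in mouse peritoneal macrophages, phagocytes taken from the abdominal cavity, of the inbred strain C57BL/6. Cells were left untreated or were exposed for 24 h to 1 of 2 ligands of Toll-like receptors. The labels give no culture time for the untreated cells. Poly I:C, a synthetic double-stranded RNA that activates TLR3, was given at 2 ug/mL. PAM, a lipopeptide ligand of TLR2, was given at 1 ug/mL, and the labels of its 2 samples name the compound differently. Each of the 3 groups held 2 arrays, so 6 arrays were compared. The labels do not say whether the 2 samples of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision: the median standard error of a log2 difference between groups was 0.07. After assignment of probes to single genes, 19935 genes were tested. Differences are given as log2 value ± SE (n = 2 arrays per group), with adjusted p from limma. The log base of the deposited values was taken as 2, and every fold rests on that.

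The comparison of poly I:C with untreated cells asked which genes the TLR3 ligand moved. Genes of the interferon response were among the largest increases. Ms4a4c, a membrane-spanning protein gene, rose by 7.54 ± 0.11, which is 187-fold (adjusted p = 9.6e-10, limma). The chemokine gene Cxcl10 rose by 7.29 ± 0.14, and Ifit3, Ifit2 and Ifit1, which encode antiviral RNA-binding proteins, rose by 6.86, 6.56 and 6.12. Ifi206 (7.12), Ifi205 (6.26), Ifit3b (6.11), AW112010 (6.23) and Acod1, the enzyme that makes itaconate (6.60), completed the 10 largest increases. The largest decreases were those of Mamdc2 (-4.56 ± 0.08), Cmbl (-3.79) and the sorting receptor gene Sort1 (-3.54). Rgs18 (-3.31), Idi1 (-3.28), Mrc1, the mannose receptor (-3.27), Abca9 (-3.24), Sesn1 (-3.17), Sqle (-3.16) and Rasgrp3 (-3.03) followed.

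Among the gene lists fixed before the data were examined, all 41 measured interferon-stimulated genes rose with poly I:C, with a median of 3.37, and 41 also rose when adjusted over the list alone (camera adjusted p = 6.93e-49; adjusted p = 0.277 with an estimated correlation). All 8 interferon-induced GTPase genes rose, 8 of them when adjusted over the list alone, with Gbp5 at 5.94 ± 0.10 and Iigp1 at 5.39 (adjusted p = 5.5e-14; 0.277 as the adjusted p with an estimated correlation). All 6 interferon-type chemokine genes rose, also 6 when adjusted over the list alone, among them Ccl5 at 6.09 ± 0.31 (adjusted p = 1.69e-08; adjusted p = 0.277 with an estimated correlation). Of 15 genes of MHC class I antigen presentation, 14 rose and 1 fell, with the same counts when adjusted over the list alone. Tap1, a peptide transporter, rose by 3.24 and Tapbpl by 3.01, while Calr, a chaperone gene, fell (-0.75; camera adjusted p = 4.07e-15; adjusted p = 0.277 with an estimated correlation). Of 8 MHC class II genes 7 rose, 7 also when adjusted over the list alone, with H2-Ab1 at 1.27 and H2-Oa at 1.31 (adjusted p = 3.16e-05; adjusted p = 0.364 with an estimated correlation). Of 17 costimulatory and checkpoint ligand genes 15 rose, and 16 when adjusted over the list alone, led by Cd86 (4.74) and Cd40 (4.60; adjusted p = 1.56e-14; adjusted p = 0.277 with an estimated correlation).

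The NF-kB subunit and feedback list rose too, with 18 of 21 genes higher and 1 lower (19 and 1 when adjusted over the list alone). Traf1 stood at 2.64, Nfkbie at 2.64 and Dusp2 at -0.55 (adjusted p = 5.17e-14; adjusted p = 0.277 with an estimated correlation). Of 32 inflammatory cytokine, chemokine and enzyme genes 19 rose and 1 fell (20 and 1 when adjusted over the list alone). Nos2, the inducible nitric oxide synthase, rose by 4.40 ± 0.10 and Tnf by 2.20, Ccl3 fell (-0.27), Il1b rose (0.32), and the difference of Il6 was 0.33 without passing (list adjusted p = 9.53e-10; adjusted p = 0.364 with an estimated correlation). Of 20 cell death and inflammasome genes 12 rose and 5 fell, also 12 and 5 when adjusted over the list alone. Tnfsf10, which encodes the death ligand TRAIL, rose by 5.65 ± 0.14 and Casp4 by 3.12, whereas Bcl2 (-1.06) and Bcl2l1 (-0.73), both inhibitors of apoptosis, fell (adjusted p = 6.04e-05; adjusted p = 0.364 with an estimated correlation). Of 26 Toll-like receptor signalling genes 13 rose and 6 fell (14 and 7 when adjusted over the list alone). Tlr2 rose by 3.29 ± 0.12, Tlr9 by 2.46 and Tlr3 by 2.46, while Cd14 (-1.28) and Cd36 (-0.79) fell (adjusted p = 0.011; adjusted p = 0.493 with an estimated correlation). Ifnb1 and Ifna4, the interferon genes always reported here, stayed within error at this time. Ifnb1 differed by 0.05 ± 0.07 and Ifna4 by 0.04 ± 0.07, and Il10 by -0.03 ± 0.08. Interferon genes were not tested as a group, and signal over background is unknown for these probes.

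Cholesterol biosynthesis genes fell as a group with poly I:C. All 18 measured members were lower, 18 also when adjusted over the list alone, with a median of -1.86. Idi1 and Sqle, 2 enzymes of the pathway, fell by 9.71-fold and 8.91-fold (list adjusted p = 6.57e-20; adjusted p = 0.277 with an estimated correlation). Of 12 LXR targets and lipid efflux genes 9 fell and 1 rose (9 and 3 when adjusted over the list alone). The desaturase genes Scd2 and Scd1 differed by -2.79 and -2.74, and Nr1h3, which encodes an LXR receptor, rose (0.79; adjusted p = 0.000711; adjusted p = 0.491 with an estimated correlation). Of 29 oxidative phosphorylation genes 14 fell and 1 rose (15 and 1 when adjusted over the list alone), with Ndufa4 at -0.74 and Ndufs1 at -0.60 (adjusted p = 0.0145; adjusted p = 0.606 with an estimated correlation). Of 16 NRF2 target and metallothionein genes 8 fell and 1 rose, also 8 and 1 when adjusted over the list alone. Mt2 (-2.28) and Mt1 (-1.77) bind metals, and the cystine transporter gene Slc7a11 was the member that rose (1.39; adjusted p = 0.011; adjusted p = 0.315 with an estimated correlation). Of 29 cell cycle genes 11 fell and 3 rose (12 and 3 when adjusted over the list alone), with Pcna at -0.77, Rrm1 at -0.65 and Ccne1 at 1.41 (adjusted p = 0.0495; adjusted p = 0.628 with an estimated correlation). This cell cycle call ended with arrays centred (camera adjusted p = 0.0517) and in 5 of the 6 fits without 1 array, and the oxidative phosphorylation call ended without control replicate 2 (camera adjusted p = 0.0615).

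Other lists moved both ways and did not pass as groups with poly I:C. In the unfolded protein response list 6 genes rose, among them Trib3 (2.15) and Ddit3 (2.05), and 10 fell, among them Sdf2l1 (-1.50) and Pdia6 (-0.81); its median was -0.30 and its mean 0.03 (camera adjusted p = 0.283). The complement and scavenger receptor list held 9 higher and 11 lower genes, with Cfb at 4.84, Axl at 3.31 and C5ar1 at -2.61 (adjusted p = 0.319). In the alternative activation list 4 rose and 5 fell, and Arg1, the arginase gene, differed by -0.37 without passing (adjusted p = 0.504). In the glycolysis and hypoxia list 7 rose and 9 fell (adjusted p = 0.89), and in the lysosomal list 6 rose and 11 fell (adjusted p = 0.507). The eicosanoid list held 6 higher genes, with Ptges at 3.51, and 9 lower genes, with Tbxas1 at -1.57; its median was -0.29 and its mean 0.07 (adjusted p = 0.739). The histone list had 1 higher and 3 lower genes (adjusted p = 0.207). Resident peritoneal macrophage genes divided into 7 higher, with Timd4 at 2.44, and 9 lower, with Cd93 at -2.09 (adjusted p = 0.76), and general macrophage identity genes into 4 higher and 7 lower (adjusted p = 0.154). Markers of other cells mostly did not pass: 3 of 14 B cell markers rose and 1 fell, 1 of 16 T and NK cell markers rose and 1 fell, and 2 of 14 neutrophil markers rose and 2 fell. Of 10 mast cell markers 1 rose, Hdc, of 10 dendritic cell markers 3 rose, and of 6 eosinophil markers 1 fell. Of 15 mesothelial and fibroblast markers 5 fell, and none of 6 erythroid and platelet markers passed by limma. Median and mean also differed in sign for the resident macrophage (-0.04 and 0.04), eosinophil (0.06 and -0.09) and erythroid lists (0.01 and -0.01); camera took the sign of the median for the first and that of the mean for the others.

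Over all genes, 2421 were higher and 3638 lower with poly I:C at an adjusted p under 0.05. At least 2-fold changes were fewer, with 552 genes higher and 408 lower. Each of these genes had both arrays of one group beyond both of the other. Chance gives such a separation in 33.3% of groupings, but the threshold itself selects genes with a large difference relative to their spread. The separation therefore adds no support to these calls.

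The comparison of PAM with untreated cells asked the same of the TLR2 ligand. Chemokine and interleukin 1 genes were among the largest increases. Cxcl3 rose by 7.29 ± 0.10, which is 156-fold (adjusted p = 4.61e-10, limma), Cxcl2 by 6.70, and the interleukin 1 genes Il1b and Il1a by 6.97 and 5.18. Acod1 (6.60), the fatty acid receptor gene Gpr84 (6.14), H2-M2 (5.96), the siderophore-binding protein gene Lcn2 (5.93), the lectin receptor gene Clec4e (5.52) and haptoglobin, Hp (5.29), made up the rest of the 10 largest increases. Mamdc2 (-3.96 ± 0.08) and Cmbl (-3.88) fell most, as they did with poly I:C. They were followed by Gask1b (-3.68), the prostaglandin D synthase gene Hpgds (-3.55), Rgs2 (-3.50), the complement gene C1qb (-3.34), Cd300a (-3.31), Daglb (-3.13), Rgs1 (-3.11) and Emp1 (-3.06).

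Of the 32 inflammatory cytokine, chemokine and enzyme genes 28 rose with PAM and none fell, with 29 when adjusted over the list alone and a median of 1.64. Tnf stood at 4.43 ± 0.12, Il6 at 4.43 and Nos2 at 1.14, whereas Il10 differed by -0.02 without passing (list adjusted p = 3.66e-26; adjusted p = 0.277 with an estimated correlation). Of 21 NF-kB genes 19 rose and 2 fell, also 19 and 2 when adjusted over the list alone. Traf1 (3.31) and Nfkbiz (3.16) rose most, and the phosphatase genes Dusp1 (-0.60) and Dusp2 (-0.48) fell (adjusted p = 9.41e-19; adjusted p = 0.277 with an estimated correlation). Interferon-stimulated genes rose as well, 37 of 41 (39 when adjusted over the list alone, with 1 lower), with a median of 1.04. Ifi205 stood at 4.79 and Ifit1 at 2.84, while Ifnb1 differed by -0.02 ± 0.07 without passing (list adjusted p = 1.11e-24; adjusted p = 0.277 with an estimated correlation). Of the 8 GTPase genes 7 rose, 7 also when adjusted over the list alone, with Gbp5 at 3.66 (adjusted p = 3.23e-07; adjusted p = 0.29 with an estimated correlation). Of the 6 interferon-type chemokines 3 rose, 3 also when adjusted over the list alone, with Ccl5 at 4.09 and Cxcl10 at 2.84 (adjusted p = 0.0191; adjusted p = 0.493 with an estimated correlation). Of 15 MHC class I genes 11 rose (13 when adjusted over the list alone), with Psme2 at 1.23 (adjusted p = 1.22e-09; adjusted p = 0.29 with an estimated correlation). Of 17 costimulatory genes 10 rose and 1, the cytokine gene Il15, fell (-1.19; 12 and 1 when adjusted over the list alone). Icam1 stood at 2.81 (adjusted p = 3.76e-07; adjusted p = 0.277 with an estimated correlation).

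Stress response genes rose with PAM. Of 18 unfolded protein response genes 13 rose and 1 fell (14 and 1 when adjusted over the list alone). Asns, which makes asparagine, stood at 1.70 and Herpud1 rose 2.31-fold, while Atf3 fell (-1.25; adjusted p = 2.52e-06; adjusted p = 0.29 with an estimated correlation). Of 16 NRF2 target and metallothionein genes 10 rose and 2 fell (12 and 2 when adjusted over the list alone). Slc7a11 rose by 5.14 ± 0.09 and Gclm, a subunit of the enzyme that starts glutathione synthesis, by 1.67, while the iron exporter gene Slc40a1 (-1.25) and Mt1 (-0.25) fell (adjusted p = 2.38e-06; adjusted p = 0.277 with an estimated correlation). Lower groups were the lysosomal genes, with 14 of 25 lower and 4 higher (16 and 4 when adjusted over the list alone), among them Atp6v0d2 (-1.36) and Lgmn (-1.33; adjusted p = 0.00102; adjusted p = 0.376 with an estimated correlation). Of 22 complement and scavenger receptor genes 13 fell and 6 rose, also 13 and 6 when adjusted over the list alone. C1qb and C1qc (-2.85) encode chains of the complement component C1q, whereas Cfb (4.70) and the scavenger receptor gene Olr1 (4.41) rose; C1qb fell by 10.1-fold (adjusted p = 0.011; adjusted p = 0.472 with an estimated correlation). Of 29 cell cycle genes 11 fell and 3 rose (13 and 3 when adjusted over the list alone), with Pcna at -1.08 and Mki67 at 1.65 (adjusted p = 0.0197; adjusted p = 0.564 with an estimated correlation). The cell cycle call with PAM ended without control replicate 2 (camera adjusted p = 0.167) and without PAM replicate 1 (0.0639), and the complement call ended without control replicate 2 (0.0523).

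The remaining lists did not pass as groups with PAM. The cholesterol biosynthesis list held 4 higher and 6 lower genes, with Hmgcs1 at -0.53 and Mvd at 0.51 (camera adjusted p = 0.545). The Toll-like receptor list held 10 higher genes, with Tlr2 at 4.15 and Cd14 at 2.39, and 7 lower ones (adjusted p = 0.402), and Tlr3 differed by -0.29 without passing. Arg1, the arginase gene, rose by 1.19 with PAM. The MHC class II (2 higher and 1 lower), cell death (7 and 7), alternative activation (3 and 5), LXR (3 and 5), glycolysis (7 and 3), oxidative phosphorylation (3 and 2), eicosanoid (5 and 6) and histone lists (1 and 3) had adjusted p values from 0.0552 to 0.982. Resident peritoneal macrophage genes split into 7 higher and 9 lower, with Serpinb2 at 4.64 and Cd93 at -2.77, and general identity genes into 5 higher and 7 lower. Neutrophil markers were 4 higher, including Mmp9 (3.34) and S100a8 (2.04), and 2 lower, including Padi4 (-0.58), of 14. The platelet chemokine gene Pf4 rose 6.05-fold and the fibroblast gene Dcn by 0.95, each among markers of other cells that moved beside the inflammatory genes. Of the other cell markers, 3 B cell markers rose and 2 fell, 2 T and NK cell markers fell, 2 dendritic cell markers rose and 1 eosinophil marker fell. Of mesothelial and fibroblast markers 1 rose and 4 fell, 2 erythroid and platelet markers rose, and none of the 10 mast cell markers passed by limma. With PAM, median and mean differed in sign for the cell death (-0.15 and 0.17), resident macrophage (-0.20 and 0.14), LXR (0.09 and -0.24) and eicosanoid lists (-0.16 and 0.40), and in the T cell, mast cell, eosinophil, erythroid and Toll-like receptor lists, whose medians lay within 0.02 of 0. Camera gave the sign of the mean in all of these except the cell death and resident macrophage lists.

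Over all genes, 2202 were higher and 2781 lower with PAM, and 452 and 386 of them changed at least 2-fold. Without PAM replicate 1 the lower genes numbered 1828.

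**Figure D1:**
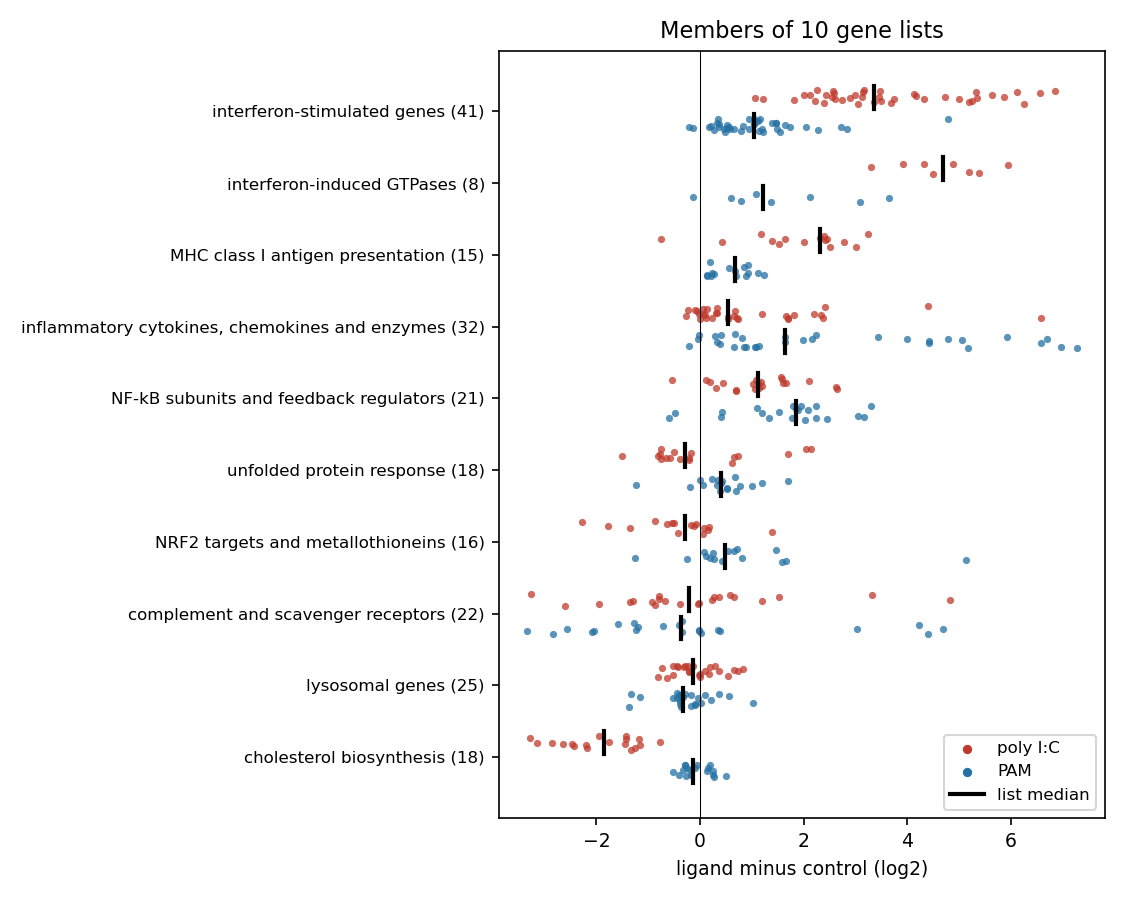
Log2 differences from control of the members of 10 gene lists, with poly I:C in red and PAM in blue; each point is 1 gene (mean of 2 arrays minus mean of 2 control arrays), black bars are list medians and the number of measured genes stands beside each list. Interferon-stimulated genes had medians of 3.37 with poly I:C and 1.04 with PAM, and cholesterol biosynthesis genes had medians of -1.86 and -0.13.

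Direct comparison of the ligands, as given at doses of 2 and 1 ug/mL, showed where the responses parted. Tnfsf10 was higher with poly I:C than with PAM by 5.80 ± 0.14, which is 55.7-fold (adjusted p = 8.26e-09, limma), followed by Ifit3b (5.75), Ms4a4c (5.66), Ifi206 (5.64), the antiviral GTPase gene Mx1 (5.30), Ifit2 (5.17), Ifi213 (5.12), Slfn1 (5.05), Slfn4 (4.89) and Isg20 (4.82). Lower with poly I:C than with PAM were Cxcl3 (-6.98 ± 0.10), Il1b (-6.64), Cxcl2 (-5.96), Lcn2 (-5.39), Acpp (-5.06), Cxcl1 (-4.85), the collagen crosslinking enzyme gene Lox (-4.79), Siglece (-4.35), Il6 (-4.09) and Il12a. Acod1 did not pass between the ligands (0.00 ± 0.06). All 41 interferon-stimulated genes were higher with poly I:C than with PAM, 41 also when adjusted over the list alone, with a median of 2.20 (adjusted p = 3.85e-42; adjusted p = 0.277 with an estimated correlation). Of the 32 inflammatory genes 20 were lower and 7 higher with poly I:C (22 and 7 when adjusted over the list alone), with Nos2 the largest of the higher ones (3.26; adjusted p = 1.83e-06; adjusted p = 0.49 with an estimated correlation). All 18 cholesterol biosynthesis genes were lower with poly I:C than with PAM, 18 also when adjusted over the list alone (adjusted p = 9.25e-21; adjusted p = 0.277 with an estimated correlation). Of 16 NRF2 and metallothionein genes 11 were lower and none higher, with 12 lower when adjusted over the list alone (adjusted p = 3.14e-10; adjusted p = 0.277 with an estimated correlation). In all, 9 lists were shifted up and 8 down between the ligands by camera with its preset correlation, and none with an estimated one. The others shifted up were the interferon-induced GTPase, interferon-type chemokine, MHC class I and II, Toll-like receptor, costimulatory, cell death and lysosomal lists. The others shifted down were the NF-kB, glycolysis, oxidative phosphorylation, unfolded protein response and eicosanoid lists. For these 13 lists the adjusted p values ran from 0.277 to 0.493 with an estimated correlation. Over all genes, 2581 were higher and 3144 lower with poly I:C than with PAM, of which 517 and 474 differed at least 2-fold.

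The series set out to find genes raised by TLR3 activation and lowered by TLR2 activation relative to untreated cells. Fcgr4, which encodes a receptor for IgG, had the largest of the smaller changes. It rose with poly I:C by 2.22 ± 0.07 and fell with PAM (-2.23 ± 0.07; adjusted p = 2.25e-08 and 3.21e-08, limma). Fcgr1, another IgG receptor gene, stood at 2.65 and -1.72 for the 2 ligands. Ly86 (1.77 and -1.93) and Cd180 (0.95 and -1.59), whose proteins form a receptor complex on the cell surface, behaved alike. Also in this group were Pld4 (1.43 and -2.18), Fgl2 (1.87 and -1.35), the cytokine gene Il15 (2.61 and -1.19), Tmem140 (2.25 and -1.14), the growth factor receptor gene Kdr (3.06 and -0.88), Cd300lf (1.54 and -1.06) and the integrin gene Itgb7 (1.42 and -1.02). Inpp1, Klra3, Themis2, Coro2a, Ifitm6, Tmem171, Rhov, Xdh and a predicted gene completed the 20 named by the smaller of their changes; the smallest of these, Xdh, stood at 0.86 and -0.89. In the reverse direction, Cd14, a coreceptor for bacterial lipids, fell with poly I:C (-1.28 ± 0.08) and rose with PAM (2.39 ± 0.08). The desaturase gene Fads2 stood at -1.85 and 1.22, Cd24a at -1.22 and 2.06, Ptgr1 at -0.99 and 1.59, and the macrophage surface receptor gene Adgre1 at -0.97 and 1.38. The collagenase gene Mmp8 fell with poly I:C (-1.12) and rose 2.82-fold with PAM. Abcc4, Agap1, Etv1, Fchsd2, Fnbp1l, Hyou1, Ifi27, Mfap3l, Nomo1, Pik3cg, Pir, Rdh11, S1pr1 and Sfxn1 completed these 20.

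**Figure D2:**
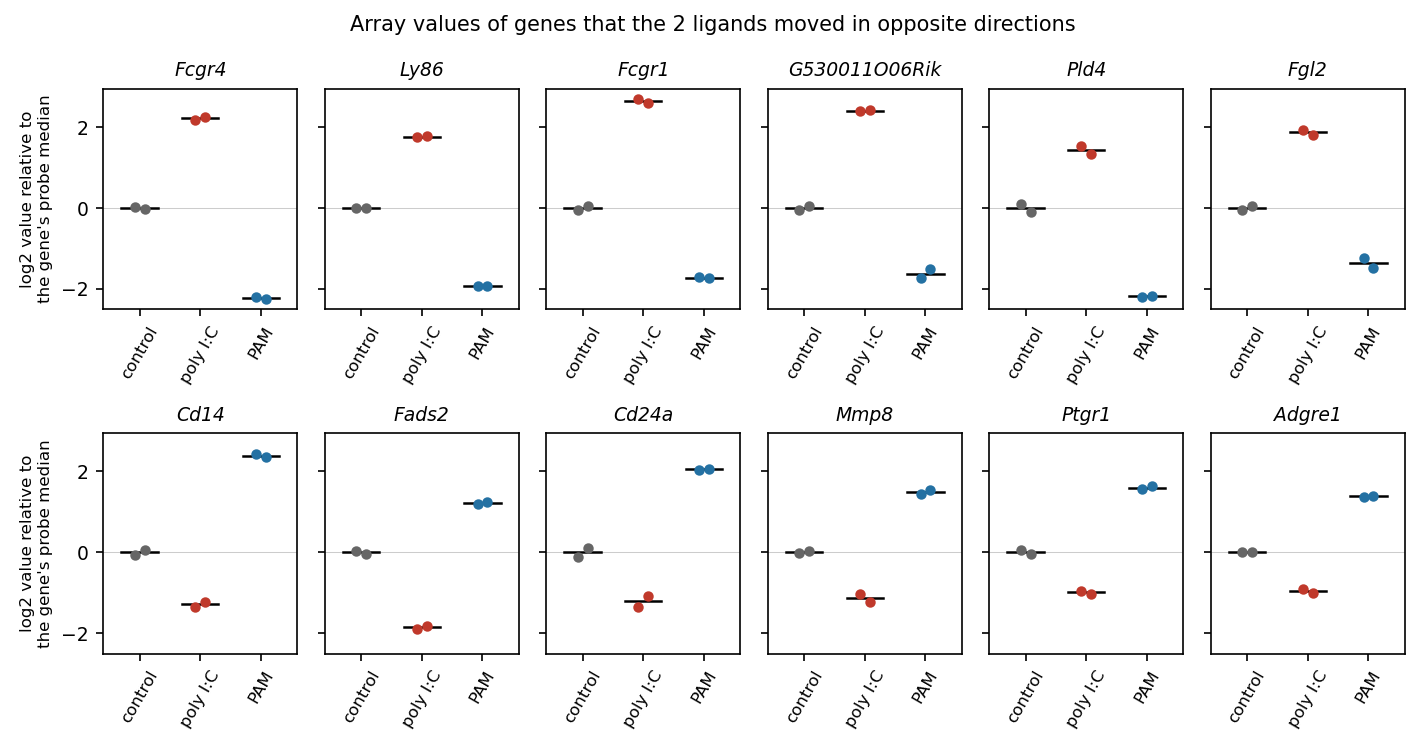
Values of 12 genes on each of the 6 arrays, as log2 relative to the median of the gene's probe over all arrays; points are arrays, black lines are means of 2, and control arrays lie near 0 because the deposited values are centred on that median. The upper row rose with poly I:C and fell with PAM (Fcgr4, 2.22 and -2.23), and the lower row did the reverse (Cd14, -1.28 and 2.39).

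In all, 270 genes rose with poly I:C and fell with PAM, where independent lists would share 337.7. Expected counts of this kind take in all 19935 genes. Genes too dim to be called with either ligand lower such counts, so the shortfall may be understated. Errors of the shared control arrays move both differences the same way and remove opposite calls, so the shortfall may also be overstated. By fold alone, 49 genes changed at least 1.5-fold each way and 14 at least 2-fold. The reverse held 374 genes (401.8 for independent lists), with 45 at 1.5-fold and 4 at 2-fold; without PAM replicate 2 the 374 became 237. Of the fixed lists, the reverse group held 7 of 18 unfolded protein response genes (one-sided Fisher's exact test, adjusted p = 1.32e-06 over 64 tests), Herpud1, Pdia6 and Sdf2l1 among them. It also held 5 of 16 NRF2 and metallothionein genes (adjusted p = 0.000267), including Gclm and Mt2, 4 of 18 cholesterol genes (adjusted p = 0.00646), including Mvd and Pmvk, and 3 of 12 LXR genes (adjusted p = 0.0203), which were Abca1, Fasn and Scd2. The group higher with poly I:C and lower with PAM held 3 of 22 complement and scavenger receptor genes (adjusted p = 0.04), Axl and, named after their values were seen, C4b and Mertk. These tests treat genes as independent and set each list against all 19935 genes, dim ones included. They were not repeated among genes at 8 or above. All 18 cholesterol genes fell with poly I:C, so their excess partly restates that fall. With PAM 4 of the 18 rose and 6 fell. The other excesses likewise partly restate calls made with each ligand alone. Of the unfolded protein response genes 10 fell with poly I:C and 13 rose with PAM, and of the NRF2 genes 8 and 10. For the LXR genes these counts were 9 and 3, and 9 complement genes rose with poly I:C while 13 fell with PAM. The tests therefore do not show that opposite moves of the same genes were linked.

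Most genes that both ligands moved went the same way. With both, 994 genes rose and 1689 fell, where independent lists would share 267.4 and 507.5. These expected counts also take in genes too dim to be called, so the excess may be overstated. A class chosen after seeing the data was genes at 8 or above on all arrays. There 744 rose with both, of 1502 higher with poly I:C and 1531 with PAM. Likewise 1186 fell with both, of 2337 and 1896. The class held 5746 genes outside the cholesterol list and 9 of that list. Overlaps expected of independent lists were not computed there, so these counts do not give the size of the remaining excess. Simulated unchanged groups with the shared controls gave 0 and 0. Hardly any unchanged gene is called, so this does not show how much the shared controls add. Acod1, Clec4e, Cfb and Tlr2 rose with each ligand (Cfb, 4.84 and 4.70), and Mamdc2, Cmbl, Mrc1 and Vsig4 fell with each (Vsig4, -1.95 and -2.06). Of the 994 shared higher genes, 338 were higher with poly I:C than with PAM and 286 higher with PAM. Across genes, which are not independent replicates, the 2 log2 differences correlated at 0.50, and 50 simulations of unchanged groups with the shared controls gave 0.50 as well. Their covariance was 0.14 against 0.0042 in the simulations, a difference of 0.13. The 2 control arrays could not be split into parts of at least 2 arrays each, so part of the excess overlap may come from the shared controls. A difference in culture time of the control cells, for which the labels give none, cannot be told apart from a response shared by both ligands.

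**Figure D3:**
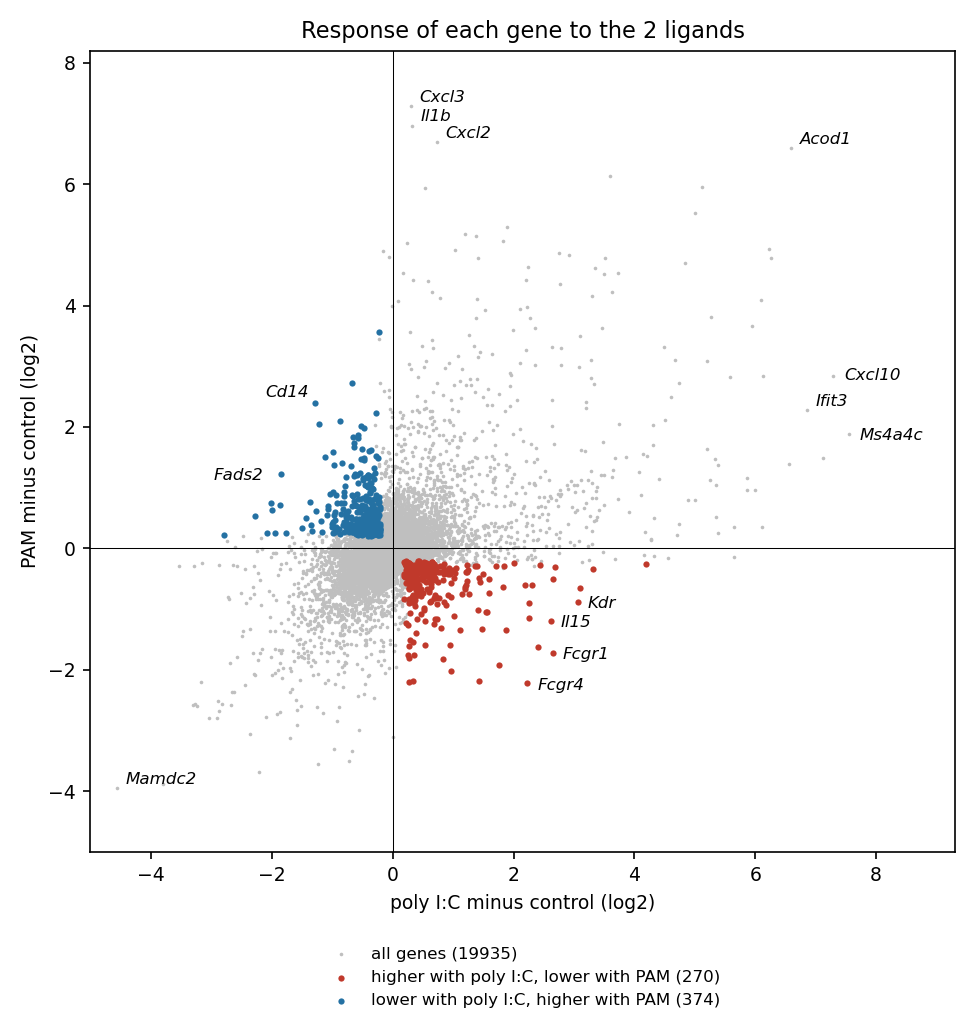
Log2 difference from control with poly I:C (horizontal axis) and with PAM (vertical axis) for 19935 genes, each point a gene (mean of 2 arrays minus mean of 2 control arrays). The 270 genes higher with poly I:C and lower with PAM are red and the 374 in the reverse direction blue, with adjusted p under 0.05 for each ligand; Fcgr4 lies at 2.22 and -2.23.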

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

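Probes outside the gene counts also carried signal above the control arrays. Among probes with no gene in the annotation, 28 were at least 4-fold higher with poly I:C than in control cells and past the threshold of limma, and 9 were with PAM. Among probes with several gene symbols, 40 were at least 4-fold higher with poly I:C and 8 with PAM. No biological explanation was tested for these probes.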

How the results depend on the processing

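No result reversed under any alternative run. Centring arrays, the variance trend, robust fitting, only the 4 arrays compared and single probes kept each count of genes between 0.86 and 1.18 of its reported value. The 40 named opposite genes stayed called under the first 4 of these and without any 1 array; single probes were run for counts only. With arrays centred the cell cycle list lost its call with poly I:C (4 lists down). Without 1 array, lists down with poly I:C numbered 4 in 5 of the 6 fits, each of which lost cell cycle. Without control replicate 2 oxidative phosphorylation also lost its call, and a list not named here gained a call. Lists down with PAM numbered 2 without control replicate 2, where cell cycle and complement lost their calls and a list not named here gained a call. They numbered 2 without PAM replicate 1, where cell cycle lost its call. With a minimum of 2-fold the counts were 552 higher and 408 lower with poly I:C, 452 and 386 with PAM, 517 and 474 between the ligands, 14 and 4 for the opposite response, and 195 higher and 159 lower with both. By fold alone, the opposite response numbered 158 and 201 at the lower planned minimum and 14 and 4 at 2-fold. With an estimated correlation 0 lists were shifted up and 0 down with poly I:C. Likewise 0 and 0 were shifted with PAM and 0 and 0 between the ligands. The preset correlation gave 10 and 5, 9 and 3, and 9 and 8. With the estimated correlation the smallest camera adjusted p was 0.277, and at 3 residual degrees of freedom that run had little power. Chosen after seeing the data, the genes at 8 or above on all arrays gave 1502 higher and 2337 lower with poly I:C, 1697 higher between the ligands, 21 and 27 opposite by 1.5-fold, 5 lists up and 1 down with poly I:C, and 3 up and 4 down between the ligands; fewer genes and shorter lists were tested there, genes that fell below 8 leave the class, and 18 of the 40 named opposite genes were called. For the other moved counts the cause was not tested, apart from the fold minimums, which remove or add genes by construction. Leaving out 1 array, with the lone array assumed to vary like the other groups, gave 1828 to 2839 genes lower with PAM, the fewest without PAM replicate 1, and 237 to 304 genes lower with poly I:C and higher with PAM, the fewest without PAM replicate 2. Deviations of same-numbered arrays correlated at -0.07, 0.15 and -0.01, which gives no clear sign of pairing by replicate number. The labels do not settle whether samples were paired. With the replicate block, 2412 genes were higher and 3614 lower with poly I:C, 2179 and 2739 with PAM, and the opposite response numbered 268 and 370. Over all alternatives, 5204 values of single named genes and 363 of lists kept their direction and side of the threshold, 99 and 64 lost the threshold and 10 genes gained it. These list values cover only lists called in the reported fit, so lists that gained a call are not among them. With the replicate block, for example, 11 lists were up with poly I:C, against 10. Not run were quantile normalization and the stricter and planned filters on dim probes, which need signal levels, offsets, which need linear values, and crossed replicate numbers, since no correlation lay under the bound set for it. Signal over background is unknown for centred values, so weak probes could not be told from strong ones except by the class at 8 or above.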

Other observations

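The families in this and the next paragraph were chosen after the data were seen, and some definitions were narrowed once their members had been listed. They were tested for excess of called genes by one-sided Fisher's exact tests, adjusted over 132 tests, which treat genes as independent. Members were matched by name. Many members of some families rose with poly I:C, and a link of these families to interferon was not tested. They were 8 of 9 Schlafen symbols (Slfn1 6.00, Slfn4 5.85, Fisher adjusted p = 8.28e-06) and 8 of 10 genes of the interferon-inducible p200 family (Ifi213 5.38, adjusted p = 2.77e-05). Also higher were 7 of 11 PARP genes (Parp10 2.77, adjusted p = 0.00077) and 10 of 19 Ms4a genes (Ms4a6b 4.28, adjusted p = 0.000268). With PAM 5 Schlafen genes rose and 0 fell (adjusted p = 0.00829 for the higher genes), 5 PARP genes rose and 2 fell (adjusted p = 0.0193) and 6 Ms4a genes rose and 1 fell (adjusted p = 0.0488). The p200 family split evenly with PAM, with 3 higher and 3 lower, neither in excess (adjusted p = 0.231 and 0.337). Some of these genes also stand in the fixed interferon list. Proteasome subunit and activator genes rose with both ligands, 31 of 43 with poly I:C and 36 with PAM (adjusted p = 8e-18 and 5.23e-26), with medians of 0.45 and 0.38, and so did aminoacyl-tRNA synthetase genes, 12 and 15 of 16 (adjusted p = 3.01e-07 and 2.65e-12). Of these 16, Hars (-0.27) and Iars (-0.26) fell with poly I:C, as did Farsb (-0.58), which the match by name left out. Ribosomal protein genes were lower with poly I:C, 33 of 60, by a median of -0.22 (adjusted p = 5.89e-09; also -0.22 with arrays centred), and 16 of 60 were lower with PAM (adjusted p = 0.0281). Against genes at 8 or above on all arrays only, the excess of lower ribosomal protein genes held with poly I:C (29 of 49, adjusted p = 0.00658) but not with PAM (15 of 49, adjusted p = 0.728), and both the proteasome and the synthetase excess held with each ligand (largest adjusted p = 0.000874).

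Surface receptor families divided within themselves. Of 4 Fc gamma receptor genes 3 rose with poly I:C (adjusted p = 0.0277) and 3 fell with PAM (adjusted p = 0.0366), but they were not the same 3: Fcgr3 fell with both (-2.04 and -0.70) and Fcgr2b, an inhibitory receptor, rose with both (0.77 and 1.88). All 4 Cd200 receptor genes were higher with poly I:C than with PAM (adjusted p = 0.00218). Of 8 Cd300 genes 5 fell with PAM (adjusted p = 0.0108), while Cd300e rose (3.06). Of 16 symbols of solute carrier family 7, which holds amino acid transporters and by name also Slc7a6os, which is none and did not pass, 7 rose with poly I:C and 8 with PAM (adjusted p = 0.00895 and 0.00102), including the arginine transporter gene Slc7a2 (2.92 and 4.83). Glutathione S-transferase genes were lower with poly I:C, 9 of 19 (adjusted p = 0.0168), and Gstp1 moved in opposite directions (-1.26 and 0.62). Against genes at 8 or above on all arrays, where few members remain, neither the transferase nor the solute carrier excess held (smallest Fisher adjusted p = 0.0637). The Cd300 excess did (4 of 4, adjusted p = 0.0435). With poly I:C the Schlafen and Ms4a excess held there (each 5 of 5, adjusted p = 0.00884). That of PARP genes (3 of 6, adjusted p = 0.395) and of p200 genes (3 of 3, adjusted p = 0.0783) did not. With PAM none of these 4 held there (smallest adjusted p = 0.0637), and neither did the Fc gamma or Cd200 receptor excess with any comparison. Genes dim in control cells leave this class even where a ligand raised them. An excess that did not hold there therefore does not show a weaker response of the family.

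Of the tests below, those of an array-wide shift, of bright probes, of mixed RNA and of a weaker copy were chosen after the result was seen. The fall of all 18 cholesterol biosynthesis genes with poly I:C was set against 2 technical explanations. The median of all genes, 0.0081, showed no array-wide shift in the deposited values. Array medians already lay near 0 there, so it could hardly come out otherwise and does not test the normalization. Compression of bright probes is argued against by 7435 genes outside the list read as at 8 or above on control and PAM arrays. Values of poly I:C arrays do not enter this class, and it holds all 18 list genes. The median of the 7435 genes was -0.0462, with quartiles of -0.31 and 0.14. Of them 6.16% fell as far as the least lowered list gene (-0.78). The class takes in dimmer probes too (12.7% of olfactory receptor probes), which may pull these values toward 0. The class planned first, at 8 or above on all 6 arrays, loses genes that fell below 8 and held 9 of the 18, so it decides nothing. A candidate explanation is the induction of Ch25h, whose product, 25-hydroxycholesterol, is known to block processing of the transcription factor SREBP: Ch25h rose by 4.48 with poly I:C and 3.31 with PAM and was higher with poly I:C by 1.17 (adjusted p = 0.000264, limma). It was raised 9.94-fold by PAM too, where the list did not fall as a group, so this hypothesis would need a threshold or another factor, which was not tested.

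Within the unfolded protein response list, chaperone genes of the endoplasmic reticulum (ER) such as Sdf2l1 and Pdia6 fell with poly I:C. Genes linked to the transcription factor ATF4, such as Trib3 and Ddit3, rose. This division was drawn after the values were seen and was not tested within the list. In genes outside the list, 18 of 30 ATF4-linked genes rose and 1 fell, and 12 of 34 ER folding and translocation genes fell and 2 rose. The medians differed by 0.54 (permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give). This is what 2 programmes that move apart would give. The permutations treat genes as independent, which genes of 1 pathway are not, so these p-values do not measure the spread between arrays. With PAM 22 ATF4-linked genes were higher and 0 lower. Of the ER genes 11 were higher with PAM, 1 lower and the other 22 not past the threshold. Medians with PAM were 0.41 and 0.16, a difference of 0.25 (permutation p = 0.0141). Genes whose values had been seen were kept out of both sets, except that Cebpb was removed only after a first computation that held it (0.55), and 3 synthetase genes kept out had fallen (Farsb -0.58), as had the ER genes kept out; with these 4 and the other tRNA synthetase genes matched by name added, the difference was 0.51 (permutation p = 1e-05). A general fall of abundant transcripts stays open for the ER part: the ER set lay below genes at 8 or above by -0.11, where random draws of the same size lay at least as far off in a share of 0.125, so neither bound set beforehand was met, and that class too loses genes that fell below 8.

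Interferon-stimulated genes rose with PAM, and Ifnb1 did not pass. With poly I:C Ifnb1 stayed within error too, while all 41 of these genes rose. Ifnb1 at this time therefore does not show whether interferon took part in the PAM response. Poly I:C RNA mixed into the PAM samples would give each gene a like share, but among 38 genes raised at least 4-fold by poly I:C the implied share ran from 1.58% to 23.9% between the 10th and 90th percentiles, a ratio of 15.2, with Ifi205 at 35.3% and Mx1 at 0.55%. Whether the PAM response is a weaker copy of the poly I:C response stays open: across the 41 genes, which are not independent replicates, Spearman's rho was 0.60 with shared controls, and 0.62 and 0.60 with a separate control array for each ligand, between the bounds set for the test.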
